A study of Drosophila melanogaster with 3 samples.

How the data were processed

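Chromatin immunoprecipitation followed by sequencing was analysed from whole Drosophila melanogaster embryos of mixed sex, 2 to 4 h old, of a transgenic line that carries Neu2 with GFP fused to its C-terminus. Per the labels, the precipitation used an anti-GFP antibody, chromatin was sheared by sonication and fragments ranged from 200 to 800 bp. The 3 libraries were labelled as biological replicates and formed a single group, so no comparison between groups of samples was possible and all comparisons were made between genomic positions.

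The authors deposited peak lists on the dm6 and the dm3 builds. Each replicate had a relaxed list that held peaks and background together, made as input for the irreproducible discovery rate (IDR) procedure, the pooled replicates had a list of the same kind, and an optimal list held the peaks past the authors' IDR threshold. Per the text that accompanied the deposited files, peaks were called against a control. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here, and the control library was not analysed here. The deposited signal value of each call was the authors' own and was used to rank, filter and describe peaks within a list. The deposited −log10 q-value reached a ceiling in each list (3.39 for the optimal dm6 list, shared by 1240 peaks) and was used only for description. The summit offset that the authors deposited for each call (another measure, in bp) gave the summit position. The lists held no read counts, so the depth of each library was unknown and no interval that needs it was given. Confidence intervals (95%, exact Clopper-Pearson) cover the counting error of peaks or genes only.

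All analyses other than the comparison of builds used the dm6 lists, the dm6 reference genome and the Ensembl release 115 annotation (BDGP annotation 6.54), restricted to the 6 main arms 2L, 2R, 3L, 3R, 4 and X. No coordinate was converted between builds, and no dm3 reference was used here. Because the relaxed lists of dm6 all held 30000 calls, replicate support was measured against the 1471 calls of highest signal in each replicate, as many as the optimal list held, and a peak counted as matched when a summit lay within 200 bp. Signal per replicate was divided by the median signal of that replicate at the optimal peaks before it was averaged, and is given as relative signal. Promoters were the positions within 500 bp of a transcription start site (TSS) of a protein-coding gene. The remaining positions were assigned in the order 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Relaxed pooled calls more than 1000 bp away from an optimal peak served as background.

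Positions were tested by 10000 circular shifts of the summits along each arm, for which the smallest possible p was 0.0001 in a one-sided test and 0.0002 in a two-sided test. Shares were also set against the relaxed calls with Fisher's exact test (two-sided), and arm counts against arm length with an exact binomial test (two-sided). A gene counted as carrying a peak when an optimal summit lay within 1000 bp of a TSS. The 17 gene lists were each set against all other protein-coding genes (13945 genes in all) with Fisher's exact test (two-sided). Listed symbols absent from the annotation were matched through a synonym list in 4 cases. Words of 6 bases were ranked on 2L and 3R by comparing the windows reaching 50 bp to either side of each summit with windows centred 300 bp away, and the 10 best were tested on 2R, 3L and X. The 15 known words were tested on all arms. Both word tests used one-sided Fisher's exact tests. The signal of promoter and other peaks was compared by a two-sided permutation test of the medians with 100000 resamples. Adjusted p-values were Benjamini-Hochberg values within each family, with a threshold of 0.05.

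Gene lists, words, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 20 optimal peaks of highest signal that were matched in every replicate, each by its nearest protein-coding TSS, up to 4 members of each gene list with the highest signal, Neu2 itself, and the 2 peaks of highest signal in each feature class other than promoter. The alternatives were stricter peak sets, leaving out each replicate, other matching distances, TSS windows, backgrounds, word lengths and windows, and the dm3 lists. Since the authors made the optimal list from all 3 libraries, leaving out a replicate meant keeping the optimal peaks matched in both of the others.

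Scripts were tested on simulated data. In 100 simulated sets of 1500 uniformly placed summits, the circular shift test of promoters gave p under 0.05 in 4. With a share of summits planted at TSSs, 38.3% of simulated summits lay at promoters against 10.3% without planting. In 20 simulated sets with no gene list planted, 1 call was made over the 17 lists. A planted word was found and held on the held-out arms, and 0 words passed without planting. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.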

Results

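Binding of Neu2, a zinc-finger protein of the ZAD family, was profiled in 3 biological replicates of 2 to 4 h embryos. The optimal dm6 list held 1471 peaks, all on the main arms. Their signal ranged from 88.6 to 998 with a median of 119. These were exactly the 1471 calls of highest signal in the pooled list. Depth per library could not be read from the lists. At the optimal peaks the median signal was 47.0 in replicate 1, 47.8 in replicate 2 and 33.1 in replicate 3, on scales that differ between libraries.

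The first question was which sites were bound and how far the replicates shared them. The strongest peak lay at -187 bp relative to the nearest TSS, that of px (plexus, FBgn0003175), a gene named for its wing-vein phenotype, at 2R from 22514115 to 22514487, with a signal of 998 and a relative signal of 7.69 ± 0.868 (SD, n = 3). The peak of second rank lay in an intron at -1377 bp relative to the nearest TSS, that of cbt (cabut, FBgn0043364), a zinc-finger transcription factor, at 2L from 480916 to 481275, with a relative signal of 7.02 ± 0.741 (SD, n = 3). SERCA (FBgn0263006), the calcium pump of the endoplasmic reticulum, followed with a promoter peak at 2R from 23933429 to 23933898 and a relative signal of 6.77 ± 0.420 (SD, n = 3). Calr (FBgn0005585), the calcium-binding chaperone calreticulin, had a promoter peak at 3R from 9630616 to 9631038, with a relative signal of 6.22 ± 0.428 (SD, n = 3). The promoter peak of Ugalt, a UDP-galactose transporter, was at X from 2703722 to 2704057 with a relative signal of 5.89 ± 1.26 (SD, n = 3).

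The rest of the 20 strongest peaks had signals from 469 to 691. Promoter peaks among them lay at Art3, CG14100, ph-p, Glg1, Chro, CG1888, CG13921, fu, Usp10 and CtsF. ph-p encodes a Polycomb-group protein and its peak had a signal of 622, Chro encodes a chromodomain protein of interbands and domain boundaries with a signal of 553, and fu encodes the kinase of Hedgehog signalling with a signal of 518. Peaks outside promoters lay in introns nearest to Lk6 (signal 583) and CG11050 (480), in a coding exon nearest to koi (534), in a 3′ UTR nearest to tio (549) and between genes 12125 bp from CG6465 (469).

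Of the 1471 optimal peaks, 638 (43.4%) were matched in the top calls of all 3 replicates, and circular shifts of the summits matched a mean of 0.155%. No p is given for this difference, because the optimal list was made from these same libraries. Replicate 1 matched 77.6%, replicate 2 matched 71.2% and replicate 3 matched 67.8%. A further 476 peaks were matched in 2 replicates, 322 in 1 and 35 in 0. Support rose with signal. In the lowest signal decile 6 of 148 peaks (4.05%, 95% interval 1.502 to 8.61) were matched in all 3, and in the highest 147 of 147. Deciles and matching both use signal from these same libraries, so part of this rise follows from how they were defined. Within the whole relaxed lists 95.1% of optimal peaks had a call in every replicate. Across peaks, which are not independent replicates, Spearman's rho of signal was 0.446 between replicates 1 and 2, 0.508 between 1 and 3, and 0.482 between 2 and 3.

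**Figure D1:**
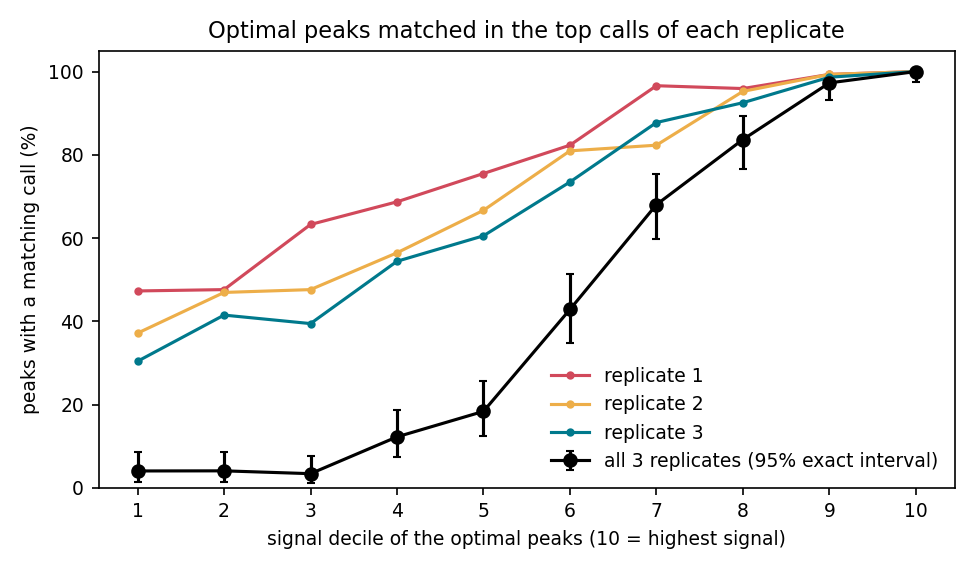
Share of optimal peaks (vertical axis, %) with a summit within 200 bp among the 1471 calls of highest signal of each replicate (coloured lines) and of all 3 (black, with exact 95% intervals), by signal decile of the optimal list (horizontal axis, 10 highest). Support in all 3 replicates went from 4.05% in the lowest decile to 100% in the highest. Deciles and matching both use signal from the same libraries, so part of the rise follows from how they were defined.

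Neu2 itself (FBgn0037085, 3L from 21484891 to 21490586, minus strand) carried 1 optimal peak, with its summit at 21490532, 54 bp from the TSS. Its signal of 91.3 ranked 1358 in the list. It was matched in the top calls of 1 replicate, replicate 2, where a call with its summit at 21490520 had a signal of 53.4 and ranked 558. In the relaxed lists, the gene and 1000 bp to either side held 9 pooled calls. Replicates 1, 2 and 3 had 5, 8 and 5 calls there. The strongest had its summit at 21489816 in replicate 1 and at 21490020 in replicate 3, away from the optimal summit. Neu2 is the tagged gene, and whether the tagged copy added to the calls at this gene was not tested.

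The next comparison asked where in the genome the peaks lay. Promoters held 794 of the 1471 summits (54.0%, 95% interval 51.4 to 56.5), against 11.5% ± 0.908 (SD over shifts) after circular shifts (two-sided permutation p = 0.0002, the smallest these shifts can give). Relaxed calls away from the optimal peaks lay at promoters in 6149 of 27565 cases (22.3%), an odds ratio of 4.08 (Fisher's exact p = 8.70e-144). Neither background was matched on transcription, so these comparisons cannot tell Neu2 binding from signal at transcribed promoters in general. Promoter summits had a median position of -75 bp relative to the TSS, and 72.0% were upstream of it. At the other end, 257 summits (17.5%) were more than 5000 bp from any protein-coding TSS.

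Coding exons held 2.52% of summits against 13.3% after shifting, 3′ UTRs 1.56% against 5.12%, introns 26.0% against 39.7% and intergenic positions 13.3% against 28.0% (adjusted permutation p = 0.00028 for each of these by two-sided circular shifts). The 5′ UTR share (0.544%, adjusted permutation p = 0.375) and the share of other exons (2.11%, adjusted permutation p = 0.222) did not pass the test. The strongest peaks of these classes lay nearest to Raf (signal 186) and Kdm4B (154) in 5′ UTRs, tio (549) and CG6340 (393) in 3′ UTRs, koi (534) and CycY (322) in coding exons, and CG4004 (361 and 348) in other exons of the X chromosome. In introns they lay nearest to cbt (904) and Lk6 (583), and between genes nearest to CG6465 (469) and CycB (435), 3316 bp from the TSS of this mitotic cyclin.

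**Figure D2:**
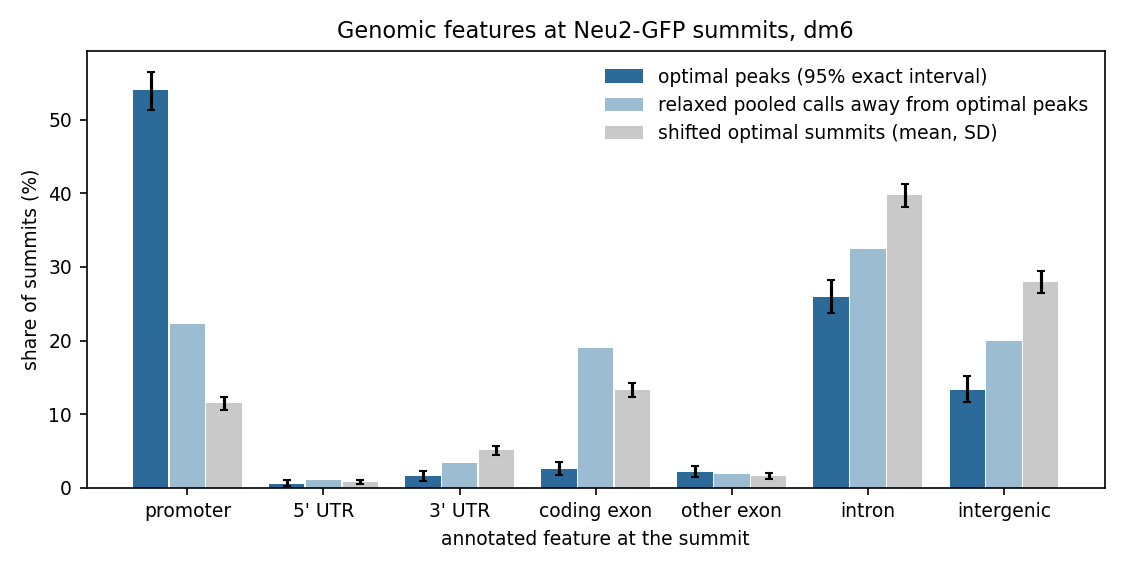
Share of summits (vertical axis, %) in each annotated feature (horizontal axis) for the optimal peaks with exact 95% intervals, for relaxed pooled calls away from optimal peaks, and for circularly shifted optimal summits as mean and SD over shifts. Promoters held 54.0% of optimal summits against 22.3% of relaxed calls and 11.5% of shifted summits.

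Promoter peaks had a median signal of 124 and other peaks one of 115, a difference of 9.09 (two-sided permutation p = 0.00216). The difference did not pass the test in any stricter peak set, with 0.791 among peaks matched in all 3 replicates (permutation p = 0.886) and 2.23 in the upper part of the list by signal (permutation p = 0.607). These sets are selected on signal, directly or through matching, which can by itself narrow a difference in signal. Whether it did was not tested.

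Among the arms, X held 221 peaks (15.02%, 95% interval 13.2 to 17.0) and made up 17.6% of the sequence (exact binomial p = 0.00923, adjusted p = 0.0554 over the 6 arms). The relaxed calls had 14.3% on X, and against them the difference did not pass Fisher's exact test (p = 0.469). Among peaks matched in all 3 replicates the X share was 18.0% (exact binomial p = 0.755). No arm passed the adjusted test.

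Gene lists asked which classes of genes were bound. Cytoplasmic ribosomal protein genes carried peaks most often: 37 of 93 (39.8%, 95% interval 29.8 to 50.5) had a summit within 1000 bp of a TSS, against 8.52% of other genes (odds ratio 7.10, adjusted Fisher's exact p = 6.29e-15). RpS19a had the strongest of these peaks (signal 298, relative signal 2.46 ± 0.857, SD, n = 3), although its summit was 444 bp from the RpS19a TSS and nearer to that of Rok. It was followed by RpL10Ab (290, 2.34 ± 0.378), RpL36 (250, 1.89 ± 0.377) and RpS27 (248, 1.96 ± 0.335), all matched in the 3 replicates. Summits lay 25 bp from the TSS of RpL10Ab and 20 bp from that of RpS27. The list passed the test in each alternative peak set and also against random lists with like numbers of TSSs (37 genes against a mean of 9.89, adjusted permutation p = 0.0034). In a list of abundantly expressed genes of other classes, added after this result was seen, 10 of 28 (35.7%, 95% interval 18.6 to 55.9) carried a peak.

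None of the other 16 lists passed. Mitochondrial ribosomal protein genes had 10 of 73 bound (13.7%, adjusted exact p = 0.539), with signals of 691 at mRpS10, 440 at mRpS23, 418 at mRpL41 and 292 at mRpS29. The peak at mRpS10 was the one named above by its nearer neighbour Art3, and the peak at mRpS23 was nearer to the TSS of CenG1A. Proteasome subunit genes had 5 of 48 (adjusted exact p = 1), with Rpn5 at a signal of 154, Prosbeta5 at 123, Rpn6 at 119 and Rpt5 at 104.7, of which the first 3 had a nearer TSS of another gene, Hat1, dgo and ave.

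None of the lists of early patterning genes passed the test near TSSs. Hox genes passed when gene bodies and 2000 bp to either side were counted (6 of 8, adjusted Fisher's exact p = 0.0019). Gene length stays open as the reason. Of 27 dorsoventral genes 3 were bound (adjusted exact p = 0.959): sna, the mesoderm determinant snail, with a signal of 402 and a relative signal of 3.37 ± 0.747 (SD, n = 3), ush with 151 and brk with 114. Of 12 gap and head-gap genes oc (117) and Kr (91.2) were bound (adjusted exact p = 0.600), of 11 segment-polarity genes wg (106, adjusted exact p = 1), and of 10 pair-rule and 8 Hox genes 0, which leaves upper 95% bounds of 30.8% and 36.9% (adjusted exact p = 1 for both). Of 12 genes of the first zygotic wave, Z600 (225) and Sry-alpha (111) had a summit within reach, each 665 bp from the TSS and that at Z600 nearer to CG7841 (adjusted exact p = 0.600).

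ZAD zinc-finger genes, the family of Neu2, had 3 of 12 bound (25%, 95% interval 5.49 to 57.2, adjusted exact p = 0.539), namely grau (204), Sry-delta (93.7) and Neu2 (91.3). The last is the tagged gene itself, and its peak was matched in 1 replicate. Architectural protein genes had 3 of 15 (adjusted exact p = 0.539), namely Chro (553), Trl (128) and Dref (121). The summit 29 bp from the Dref TSS also lay 55 bp from that of RpL13, and the peak counted for both lists. E(spl) and proneural genes had 3 of 16 (adjusted exact p = 0.539), namely E(spl)m7-HLH (126), ato (110) and E(spl)mdelta-HLH (91.2), the last nearer to CG43116. The remaining lists had tud (144) among 14 maternal and germ-plasm genes, aurA (100.2) among 12 cell-cycle genes and Hsp83 (130) among 16 heat-shock genes (adjusted exact p = 1 for each). Markers of cell types not yet formed had elav (168) among 12 neuronal genes (adjusted exact p = 1), and sls (96.3) and Zasp52 (90.5) among 12 muscle genes (adjusted exact p = 0.600).

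**Figure D3:**
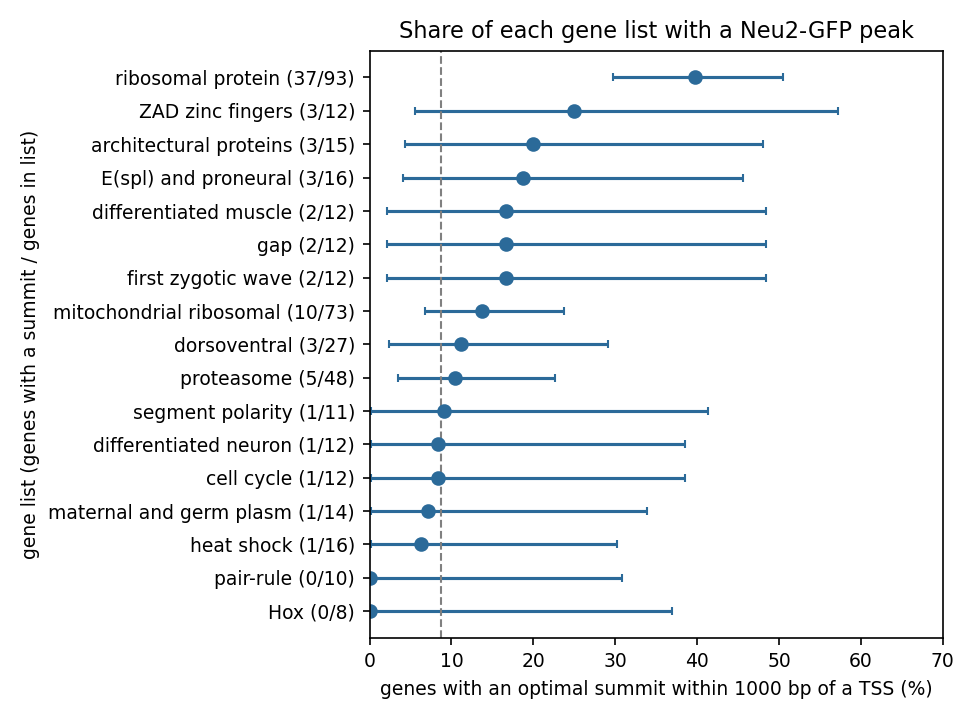
Share of the genes in each list with an optimal summit within 1000 bp of a TSS (horizontal axis, %) with exact 95% intervals, by gene list (vertical axis, with counts). The dashed line marks the share among all 13945 protein-coding genes, 8.73%, and the interval of the ribosomal protein genes, 29.8 to 50.5, lies above it.

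Sequence words asked what DNA lay under the summits. The word TATCGATA, the DNA replication-related element (DRE) that the factor Dref binds, occurred at 49 of 1471 summits (3.33%) against 0.544% of flanks (odds ratio 6.30, adjusted Fisher's exact p = 5.02e-11). The CTCF word AGGTGGCG occurred at 13 summits (0.884% against 0.102%, odds ratio 8.74, adjusted exact p = 0.000846), the core-promoter word Motif 1, GGTCACAC, at 18 (1.22% against 0.340%, odds ratio 3.63, adjusted exact p = 0.00378), and the paired CGATA word of BEAF at 7 (0.476% against 0.068%, odds ratio 7.03, adjusted exact p = 0.0308). The BEAF word did not pass among peaks matched in all 3 replicates (0.470%, adjusted exact p = 0.249). The other 11 words did not pass, among them the Zelda word CAGGTAG (0.952% against 0.714%, adjusted exact p = 0.538), the GAGA word (1.97% against 3.13%, adjusted exact p = 0.991) and the word of Su(Hw) (0.612% against 0.204%, adjusted exact p = 0.0918).

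**Figure D4:**
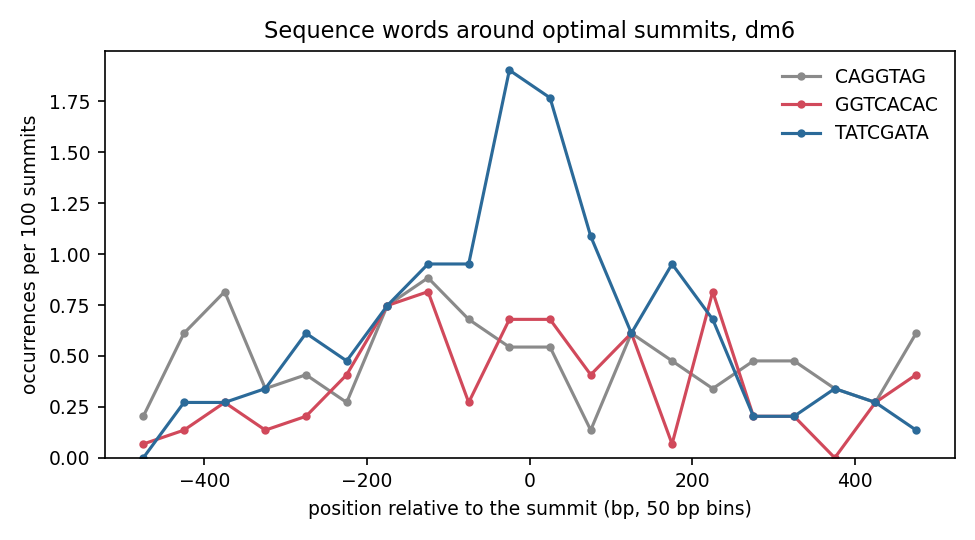
Occurrences per 100 optimal summits (vertical axis) of the DRE word TATCGATA, Motif 1 GGTCACAC and the Zelda word CAGGTAG, in bins of 50 bp by position relative to the summit (horizontal axis, bp). The DRE word reached 1.90 and 1.77 per 100 summits in the bins on either side of the summit, where the Zelda word stood at 0.544 in each.

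Of 1923 words of 6 bases tested on 2L and 3R, 37 passed, and the 10 best all passed on the held-out arms 2R, 3L and X. TATCGA, a part of the DRE, was found at 94 of 804 held-out summits (11.7% against 4.17% of flanks, odds ratio 3.05, adjusted exact p = 1.29e-10). The overlapping words CGATAG (odds ratio 3.05) and ATCGAT (2.58) had adjusted exact p = 1.64e-08 and adjusted exact p = 2.96e-07. AT-rich words followed, with ATTTAA at 23.5% of summits against 13.9% of flanks, CTTAAA at 11.9% against 6.59% and AAATAT at 22.9% against 16.4%. The words TACTAA, ACTAAA, ATACTA and AATAGT had odds ratios from 1.44 to 1.55. When words were ranked anew among peaks matched in all 3 replicates, TATCGA was not among the 10 taken, and 2 words passed, AATTTA and CTTAAA. It was also not among the 10 taken without replicate 1 or without replicate 3. TATCGA tested directly among peaks matched in all 3, a test added after this was seen, was at 41 of 372 held-out summits (11.02% against 3.76%, one-sided Fisher's exact p = 4.00e-06). In the central 51 bp 4 words passed, TATCGA among them.

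The dm3 optimal list, from the same libraries on the older build, held 1425 peaks against 1471 on dm6, 1409 of them on the main arms. X held 212 of those (15.05%).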

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

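The tests of shared peaks, and of the X share of relaxed calls, and the word CYACYAAA, were chosen after the results they bear on had been seen. The dm3 optimal list held 16 peaks on contigs outside the 6 main arms. The comparison of arms left them out, and they drew attention for that reason. They lay on 3LHet (8 peaks, highest signal 239), 3RHet (4, highest signal 171), 2RHet (2) and U (2).

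Ribosomal protein genes carried peaks at 39.8%. A single peak counted for several neighbouring genes is ruled out, since 39 distinct peaks stood behind the 37 genes and 0 of them served more than 1 gene of the list. Signal at highly transcribed genes in general remains open and may account for the pattern: among 28 abundantly expressed genes of other classes, listed before their peaks were counted, 10 (35.7%, 95% interval 18.6 to 55.9) carried a peak, and the ribosomal genes did not differ from them (odds ratio 1.19, Fisher's exact p = 0.826). Peaks were called against a control library, which was not analysed here. Whether that control removes such signal was not tested. No biological explanation was tested.

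Words at summits were weighed against promoter sequence and base composition. At promoter summits the DRE word was more frequent than at the same distances from TSSs of genes without a peak (5.79% against 2.05%, odds ratio 2.93, one-sided Fisher's exact p = 9.27e-09). The CTCF word was too (0.882% against 0.214%, odds ratio 4.15, one-sided Fisher's exact p = 0.00436). ATTTAA differed by less, with 22.9% against 18.0% (odds ratio 1.35, one-sided Fisher's exact p = 0.000575), and this included the arms on which it was found. Motif 1 did not pass (2.02% against 1.55%, one-sided Fisher's exact p = 0.194). Genes without a peak were not matched on transcription, so these tests cannot tell the summits from highly transcribed promoters in general. Shuffling the bases within each window left the DRE word in a mean of 3.84 windows against 49 observed, and ATTTAA, on the arms not used to find it, in 125 against 189 (permutation p = 0.001 for each, the smallest that 1000 shuffles can give). The shuffles broke up runs of like bases, and flanks were not shuffled. Summit windows held 60.5% A or T and flanks 56.8%. Whether this explains the excess of AT-rich words over flanks was therefore not decided. For CYACYAAA, where Y is C or T, the same tests gave an odds ratio of 3.20 and a mean of 21.99 windows against 74, but they ran on the summits the word was picked from, so promoter sequence and base composition stay open for it. The DRE word may mark sites of Neu2, of factors that share its sites or of highly transcribed promoters in general, which these lists do not separate.

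The X share of 15.02% was below the 17.6% of the sequence on X, but did not pass the adjusted test and was 18.0% among peaks matched in all 3 replicates. X held 14.3% of the relaxed calls (95% interval 13.9 to 14.8), a value known before the test was chosen, so a lower yield of X calls at any strength stays open. Embryos were of mixed sex, so a lower copy number of X stays open and was not tested.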

How the results depend on the processing

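The length-matched test of Hox genes was chosen after the results had been seen. The test of X against the relaxed calls was planned beside the main test, but was not planned as an alternative. Of 328 alternative values, 255 kept their direction and side of the threshold, or their size. Promoter share ranged from 43.8% to 62.2%, past its test throughout, and support in all 3 replicates from 36.0% to 78.3%, a value for which no test applies since the list came from these libraries. In all, 5 feature classes passed in both stricter peak sets they were run on, and ribosomal protein genes passed in each alternative. For the results that follow the cause was not tested, except that stricter peak sets hold fewer peaks. Leaving out a replicate left 758 to 826 peaks. The X share was 17.5% in the upper part of the list by signal, 18.0% among peaks matched in all 3 replicates (reversed), 16.5% to 17.4% without a replicate, 15.05% on dm3, and 15.02% against relaxed calls (reversed). The promoter difference in signal was 2.23 in the upper part of the list, 0.791 among peaks matched in all 3, and 3.16 to 5.34 without a replicate. It passed the test in none of these sets. They are selected on signal, which can by itself narrow the difference, and this was not tested. The 6-base words that passed numbered 2 among peaks matched in all 3, 4 to 7 without a replicate, and 4 in the central 51 bp. With gene bodies and 2000 bp to either side 2 lists passed, ribosomal protein and Hox genes (75%, reversed, adjusted exact p = 0.0019), and Hox was also reversed against genes of like length.

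Other lists, which passed in no setting, turned direction relative to the share among other genes as follows. In the stricter sets and those without a replicate, maternal (1 of 14) and neuronal genes (1 of 12) kept their main counts. They turned only because the share among other genes fell, from 8.73% to between 4.12% and 5.26%. Heat-shock genes at 6.25%, and cell-cycle and neuronal genes within 500 bp of a TSS, also kept their main counts. In the upper part of the list by signal, gap, segment-polarity and muscle genes had 0%, maternal 7.14%, neuronal 8.33% and heat-shock genes 6.25%. Among peaks matched in all 3, gap, muscle and E(spl) genes had 0%, dorsoventral 3.70%, maternal 7.14%, neuronal 8.33% and proteasome genes 2.08%. Without a replicate, with ranges that include sets in which the direction was kept, gap and muscle genes had 0% to 8.33%, dorsoventral 3.70% to 7.41%, maternal 7.14%, neuronal 8.33%, heat-shock 0% to 6.25%, and proteasome genes 2.08% to 6.25%. Within 500 bp of a TSS, dorsoventral genes had 3.70%, first-wave genes 0%, and cell-cycle and neuronal genes 8.33%. With gene bodies, pair-rule genes had 20%, maternal 28.6%, cell-cycle and neuronal 33.3% and proteasome genes 14.6%. Against lists matched on TSSs, dorsoventral (11.1%) and muscle genes (16.7%) turned. The Inr word was at 6.39% in the upper part, 5.96% among peaks matched in all 3, 5.45% to 7.12% without a replicate and 6.46% against more distant flanks, where CAGGCAG was at 1.22%. The BEAF word lost its call in 5 alternatives, and the word of Su(Hw) gained one in 2. Depth was unknown, so its effect on weak peaks could not be measured.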

Other observations

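The tests of CYACYAAA and of Hox gene bodies were chosen after the patterns had been seen, and the count that decided on paired promoters was changed after both of its forms had been computed. Of 6 other gene types, 4 carried optimal summits within 1000 bp of a TSS less often than the 8.73% of protein-coding genes. Transfer RNA genes had 9 of 290 (3.10%, adjusted Fisher's exact p = 0.000413), ribosomal RNA genes 0 of 99 (upper 95% bound 3.66%, adjusted p = 0.000413), pseudogenes 6 of 268 (2.24%, adjusted p = 6.89e-05) and long and other non-coding RNA genes 148 of 3261 (4.54%, adjusted p = 2e-16). The other types did not pass: small nucleolar RNA genes had 25 of 269 (9.29%, adjusted exact p = 0.743) and small nuclear RNA genes 5 of 32 (15.6%, adjusted exact p = 0.235). These tests and bounds count each gene as independent. Genes of a type that lie side by side as repeated copies were not grouped, so the p-values may be too small. Annotated transposable elements held 7 summits (0.476%) against 5.89% after circular shifts (permutation p = 0.0002, the smallest these shifts can give). Reads that map to repeats, in elements or in repeated genes, may have been removed before peaks were called, and this was not tested.

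No window of 10000 bp held more than 4 peaks, and those with 4 lay at Raf on X (all matched in the 3 replicates), pico (3 matched in all 3), ph-p, by and the pair CG4297 and cbt (2 each), and Eip75B and the group of CG3552, CG44838 and phol (1 each). These genes are named because of their counts, and whether peaks lie closer together than by chance was not tested. The promoter share fell along the pooled list, from 61.0% of the 100 strongest calls to 45.2% at ranks 1472 to 3000 and 16.5% at ranks 20001 to 29995.

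Peaks may prefer promoters with start sites on both strands. Of the genes nearest to promoter peaks, 313 of 745 (42.0%) had a TSS of another gene on the other strand within 500 bp, against 25.6% of 12918 genes without a summit within 500 bp of a TSS (odds ratio 2.11, Fisher's exact p = 3.31e-21). Counting every gene within reach of a peak gave 55.8% (odds ratio 3.67), but that count lets 1 peak at a paired promoter stand for both genes and was not used. Genes without a summit were not matched on transcription or number of TSSs, so both stay open as reasons for the difference.

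The word CYACYAAA may be a sequence recurring under Neu2 peaks. It was put together from words enriched on 2L and 3R, after its degenerate form had been scored on all arms, so the test on 2R, 3L and X is not independent. There it occurred at 32 of 804 summits (3.98%) against 1.62% of flanks (odds ratio 2.52, one-sided Fisher's exact p = 0.000437). The DRE word was concentrated at promoters, with 5.79% of promoter summits against 0.443% of others (Fisher's exact p = 6.23e-10), while CYACYAAA stood at 4.16% and 6.06% (Fisher's exact p = 0.119). TATCGA and CYACYAAA shared 7 summits, where 8.20 would be shared by chance (Fisher's exact p = 0.849).

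Hox genes had 0 of 8 bound near a TSS, but Antp, Scr, Ubx, abd-A, lab and pb had a summit in the gene body or within 2000 bp of it (6 of 8, odds ratio 17.3, adjusted Fisher's exact p = 0.0019). The median length of the 8 genes was 30563 bp against 2166 bp for all genes. Random genes of like length had a mean of 2.45 such genes among 8, below the observed 6 (two-sided permutation p = 0.0196). Hox was picked from 17 lists because its count was high, and multiplied by that number the permutation p is 0.333, so gene length stays open as the reason.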
